A study of Drosophila melanogaster with 4 samples.

How the data were processed

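Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map CP190 in whole embryos of the wild-type Drosophila melanogaster strain Oregon-R. CP190 is a zinc-finger and BTB-domain protein that DNA-binding insulator proteins recruit to chromatin. The labels place the embryos at 14 to 16 h of development, while the collection protocol gives only an upper age of 16 h. Embryos were crosslinked with formaldehyde per the labels' protocols. The series holds 4 samples, of which 2 are CP190 ChIP and 2 are input chromatin. Per the labels, input 1 served ChIP replicate 2 and input 2 served ChIP replicate 1. The inputs enter these results only through the authors' own enrichment calls, and nothing in the labels says whether the ChIP replicates came from separate embryo collections.

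Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The authors deposited lists of regions of significant enrichment, here called clusters. One list was made for each ChIP replicate, and 1 further list covers the whole series, here called the combined list. How the replicates entered the combined list, the peak caller, its thresholds and its window are not given in the sources used here. Coordinates are 1-based and lie on FlyBase release 5, per the file headers, which also give the length of every sequence. No summit is given, so midpoints were used. No read counts were used, so the sequencing depth behind each cluster is unknown and no interval for a single score is given.

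Each cluster carries 1 value with no unit named in the file. Its scale was settled from the values. When 2 was raised to the deposited value and divided by 1 constant per list, taken from the most frequent tied value, a ratio of whole numbers with a denominator of at most 2000 resulted for 4460 of 4461, 4900 of 4900 and 7953 of 7960 clusters (replicate 1, replicate 2 and combined, relative tolerance 1e-12). With base e or base 10 at most 0.51% of clusters did so. To give the constant, the most frequent value was divided by 1 of a few simple ratios. That ratio was chosen for the share fitted and then for the smallest median denominator. Ratios are in lowest terms and the constant is known only up to a simple ratio. Their terms are therefore neither counts nor strict lower bounds of the numbers divided. The values deposited by the authors are therefore treated as log2 values of an enrichment ratio and called log2 scores. What the ratio is taken over, and how the lists were scaled against each other, are not given, so scores serve to describe and rank clusters within a list.

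Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A cluster counted as shared when at least 1 bp overlapped a cluster of the other list. Overlap was set against 1000 circular shifts of the other list within each sequence, with a one-sided permutation p, which cannot fall below 0.001. Log2 scores were compared over one-to-one overlapping pairs by Spearman's rho and Pearson's r across clusters, which are not independent replicates. The 95% interval of Spearman's rho came from 1000 bootstrap draws of cluster pairs. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error over clusters and not variation between embryos. Density was tested on the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X) with exact two-sided binomial tests against arm length, adjusted over the 6 arms by Benjamini-Hochberg. The restriction to these arms was decided after the files were opened, because the heterochromatic scaffolds (the Het sequences) and the unplaced sequences U and Uextra held few clusters. Those are described separately. Spacing was set against 1000 random placements without overlap on the same arms, with a two-sided p that cannot fall below 0.002. Scores of shared and unshared clusters were compared by two-sided permutation tests over clusters (100000 resamples, smallest possible p 1e-05). Overlap was tested on simulated lists on the 4405 arm clusters of replicate 1. Planted overlaps of 60.6% and 90.5% were recovered as 60.9% and 90.6%. Kept clusters were moved by less than their length and the others were placed off the list. This therefore checks only the counting of overlaps.

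The clusters named were fixed by a rule before the data were examined. They are the 15 combined-list clusters with the highest log2 score that overlap a cluster of both replicates, and, for each replicate, the 3 longest clusters and the highest-scoring cluster that the other list lacks. Comparisons, tests and most alternatives were also fixed then. The alternatives varied the overlap rule, the score threshold, the merging of neighbouring clusters, the list and the arms counted. Further alternatives, named in the closing section, were added after seeing the data. The gene table used here is on release 6 of the genome, while the clusters are on release 5, so no gene is named and no cluster is assigned to a promoter, exon, intron or UTR. For the same reason 4 planned comparisons were not run, namely clusters at transcription start sites, genomic classes, gene lists and binding motifs.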

Results

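CP190 binding was mapped by ChIP-seq in wild-type Oregon-R embryos labelled 14 to 16 h, in 2 ChIP replicates, each called by the authors against an input sample. The stage follows gastrulation and falls in the later part of embryogenesis, when most cells have begun to differentiate. The 2 ChIP lists held 4461 and 4900 clusters of CP190 enrichment, and the authors' combined list held 7960. Clusters covered 9.47 Mb in replicate 1, 10.9 Mb in replicate 2 and 16.3 Mb in the combined list. On the 6 chromosome arms that was 7.77%, 8.93% and 13.3% of the sequence. The median cluster was 2041 bp long in replicate 1, 2077 bp in replicate 2 and 1991 bp in the combined list. The shortest cluster was 1301 bp in each replicate list and 1001 bp in the combined list. Median log2 scores were 0.59, 0.62 and 0.41 in the same order. No cluster had the same start and end in both replicate lists. Read depth is unknown for all 3 lists.

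The first comparison asked how far the 2 replicates marked the same places. Of the clusters of replicate 1, 3778 (84.7%, exact 95% interval 83.6 to 85.7%) overlapped a cluster of replicate 2. In the other direction 3748 clusters of replicate 2 (76.5%, 75.3 to 77.7%) overlapped one of replicate 1. Circular shifts gave means of 16.8% and 15.3%, and the permutation p was 0.001 in both directions, the smallest that the shifts allow. The shared sequence amounted to 8.00 Mb, or 64.9% of all sequence covered by either list. Clusters with high log2 scores were mostly found in both lists, although the highest-scoring cluster of each list was not. In the highest quartile by log2 score, 98.7% of the clusters of replicate 1 and 98.8% of those of replicate 2 were shared. The share did not fall steadily with score in replicate 1, where the lower quartiles had 89.4%, 72.5% and, for the lowest scores, 78.1%. In replicate 2 they had 92.7%, 62.9% and 51.6%.

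Sharing was similar along the large arms. For replicate 1 it ran from 82.6% on 2R to 87.8% on 2L, with 85.0% on X, and for replicate 2 from 74.7% on 3R to 77.9% on 2R, with 76.8% on X. On chromosome 4, the small and largely heterochromatic chromosome, 18 of 19 clusters of replicate 1 and 18 of 24 of replicate 2 were shared. The heterochromatic scaffolds had 24 of 31 and 24 of 30 clusters shared, and the unplaced sequence U had 15 of 25 and 15 of 28. These intervals are wide, 38.7 to 78.9% and 33.9 to 72.5% for U. As only 2 lists of 1 condition exist here, p-values describe positions within these lists, and the difference between replicates may be technical.

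The strength of enrichment also followed the same order in both replicates. Over 3666 one-to-one cluster pairs the log2 scores had a Spearman correlation of 0.818 (bootstrap over pairs, 95% interval 0.804 to 0.830) and a Pearson correlation of 0.909, across clusters. The log2 score was higher in replicate 2 for 71.3% of pairs, by a mean of 0.09 ± 0.17 (SD over pairs). The lists were scored separately, so this offset has no biological reading by itself.

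**Figure D1:**
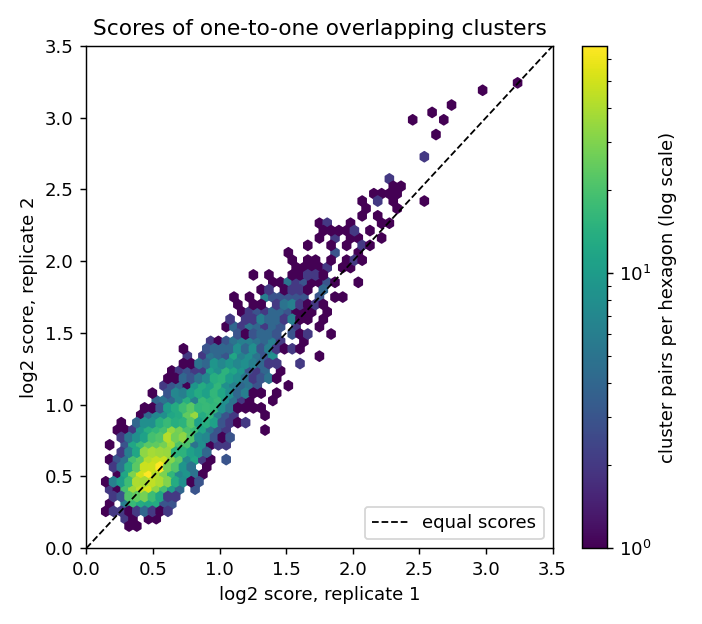
Log2 scores of the 3666 one-to-one overlapping clusters in replicate 1 (x axis) and replicate 2 (y axis), with colour for the number of pairs per hexagon on a log scale and a dashed line at equal scores. Pairs follow the line with a Spearman correlation of 0.818, and 71.3% lie above it.

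Among combined clusters found in both replicates, the 15 with the highest log2 scores lay on all 5 large arms and on 3 sequences outside them. In the whole combined list they ranked 5 to 52, as 9 of its 10 highest-scoring clusters were found in neither replicate. The first of the 15 was at 4251871 to 4254169 on U, with a log2 score of 3.18, and 3.24 in each replicate. The second was at 368804 to 371736 on 2RHet, with 3.06. The highest of the 15 on an ordinary arm was at 12519154 to 12522260 on 2L, with 2.89, which ranked 4 in both replicate lists (2.75 and 3.11). It was followed by 12085136 to 12087887 on 3R with 2.81, which ranked 6 in both (2.66 and 2.98). A cluster at 1238928 to 1240956 on 3LHet had 2.78. A further 3R cluster at 12622908 to 12625793 had 2.76, with ranks 8 and 5. On X the highest of the 15 was at 20630282 to 20632906, with 2.72 and ranks 7 and 8. On 2R the clusters at 21069333 to 21072236 and 8929198 to 8932198 had 2.58 and 2.52.

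The remaining named clusters had log2 scores from 2.32 to 2.44. They lay on X at 1846010 to 1848449, on 3L at 504553 to 507390, on 2L at 20119772 to 20122250 and 18858049 to 18860576, on 3R at 22706032 to 22708493 and on 2R at 2037546 to 2040894. All 15 named clusters ranked 2 to 20 in replicate 1 and 2 to 24 in replicate 2. Their lengths ran from 2029 to 3349 bp. What genes or regulatory elements lie there was not analysed here, since no annotation of this genome release was used.

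Clusters seen in 1 replicate alone were weaker and shorter. In replicate 1 the median log2 score was 0.63 for 3778 shared clusters and 0.50 for 683 unshared ones, a difference of 0.12. In replicate 2 the medians were 0.73 for 3748 shared and 0.47 for 1152 unshared clusters, a difference of 0.25. Shared clusters had a median length of 2088 bp against 1505 bp in replicate 1 and 2142 bp against 1732.5 bp in replicate 2. All 4 differences gave a permutation p of 1e-05 over clusters, the smallest possible, and clusters are not independent of each other.

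Some unshared clusters were nonetheless long or had high scores. The longest of replicate 1 lay on U at 5289586 to 5294862 (5277 bp), on 2R at 9559115 to 9562292 (3178 bp) and on 3L at 3059567 to 3062370 (2804 bp). Those of replicate 2 lay on 2L at 9743771 to 9747764 (3994 bp), on 3L at 6125204 to 6128967 (3764 bp) and on 3R at 9875687 to 9879370 (3684 bp). All 6 overlapped a combined cluster, and their log2 scores were between 0.29 and 0.65. The highest-scoring unshared clusters were on 3RHet at 696327 to 697778 in replicate 1 (3.59) and on U at 9305997 to 9307477 in replicate 2 (4.01). These are also the highest log2 scores of their whole lists, but their smallest whole-number ratios were 12 to 1 and 17 to 1, and neither overlaps a combined cluster.

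The combined list took up nearly all places of the replicate lists and added others. It overlapped 4361 clusters of replicate 1 (97.8%) and 4852 of replicate 2 (99.0%). Of its own clusters, 3705 (46.5%, exact 95% interval 45.4 to 47.6%) were found in both replicates, 575 in replicate 1 only and 1084 in replicate 2 only. The remaining 2596 (32.6%, 31.6 to 33.7%) were found in neither. Clusters found in both had a median log2 score of 0.63 and a median length of 2276 bp. Those found in neither had 0.36 and 1240.5 bp. Among combined clusters of at least 1301 bp, the shortest length in the replicate lists, 17.9% were found in neither replicate.

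The part without replicate support was larger outside the arms. On the arms 31.5% of 7747 combined clusters were found in neither replicate, with a range over the 5 large arms of 30.4 to 32.6%. On the heterochromatic scaffolds and U together it was 74.6% of 213 clusters (exact 95% interval 68.3 to 80.3%). These scaffold clusters were also shorter, with medians of 1129 bp on Het scaffolds and 1121.5 bp on U against 1998 bp on the arms. Among clusters of at least 1301 bp, 35.5% of 76 on the scaffolds (24.9 to 47.3%) and 17.7% on the arms were found in neither replicate. Chromosome 4 had 24 of 46 clusters of any length in neither (36.9 to 67.1%). Of the 50 combined clusters with the highest log2 score, 36 lay off the arms, 37 were found in neither replicate and 13 in both. Written as the smallest whole-number ratio, 30 of those 37 had a denominator of 1, and 0 of the 13 did.

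CP190 clusters were spread over all chromosome arms, with modest differences in density among the large arms and the lowest density on chromosome 4. Chromosome 4 had 34.0 combined clusters per Mb, 0.529 times the number that its length gives (adjusted p = 1.1e-05, exact binomial test). It was lowest in both replicates too, at 14.1 and 17.8 per Mb against 36.6 and 40.2 over all arms. Arm 2R was the densest, with 70.6 per Mb and a ratio of 1.10 (exact binomial test, adjusted p = 0.00017), and 2L was sparse at 57.6 per Mb and 0.895 (adjusted p = 1.6e-05). Both replicates gave the same direction for these 3 arms. For 3L (60.3 per Mb, 0.938), 3R (67.0, 1.04) and X (68.3, 1.06) the adjusted p-values were 0.0082, 0.046 and 0.013 in the combined list, but neither replicate list alone gave an adjusted p under 0.05.

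Clusters are unevenly spread along the arms, so the binomial test overstates certainty. When 500 kb blocks were permuted among arms, chosen after seeing the data, adjusted p-values were 0.032 for 2L, 0.046 for 2R and 0.032 for chromosome 4, and 0.17, 0.25 and 0.17 for 3L, 3R and X. Chromosome 4 holds only 3 such blocks, and how much of it reads could be placed on was not measured here. In replicate 2 alone the same permutation gave 0.087 for 2L, 0.21 for 2R and 0.033 for chromosome 4. With only the combined clusters above the median log2 score, the ratios of 2R and 3R turned to 0.992 and 0.940 and that of X rose to 1.39.

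Heterochromatic and unplaced sequences held few clusters. The 6 Het scaffolds had 10.9 combined clusters per Mb and U had 11.1, against 64.4 on the arms. In the replicate lists these sequences had 2.49 to 3.34 clusters per Mb. None was listed on Uextra, which is 29.0 Mb long, and whether reads were aligned to Uextra at all was not checked here. XHet stood apart from the other Het scaffolds, with 10 combined clusters in 0.204 Mb, 7 of them found in both replicates. Clusters on these sequences had high log2 scores, with combined medians of 0.91 on Het scaffolds and 1.18 on U against 0.41 on the arms. How much of these sequences reads could be placed on was not measured here.

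**Figure D2:**
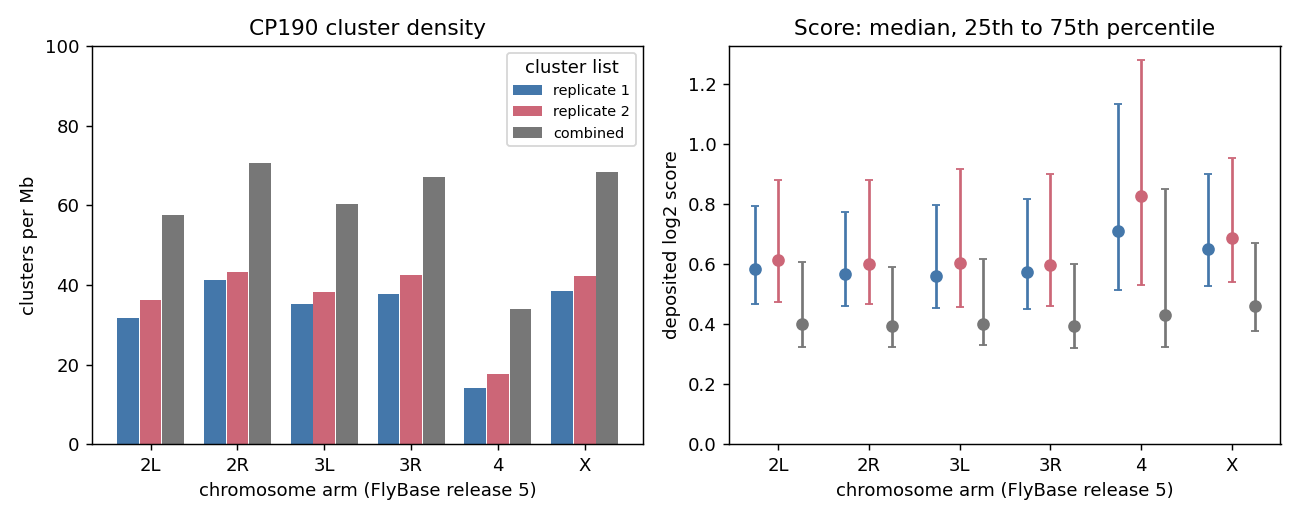
Left, clusters per Mb on each chromosome arm in the 2 replicate lists and the combined list. Right, median deposited log2 score on each arm (points) with bars from the 25th to the 75th percentile of clusters. Chromosome 4 has the lowest density (34.0 per Mb in the combined list), and X has a higher median score than each of 2L, 2R, 3L and 3R in every list.

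Neighbouring clusters lay closer together than uniform random placement over whole arms gives. Broad differences in density along an arm can also shorten these distances, and local grouping was not separated from them. Over the 6 arms the median distance between midpoints of neighbouring combined clusters was 9292 bp, against 11350 bp on average for random placement (two-sided permutation p = 0.002, the smallest possible). In the replicate lists the medians were 15935 and 14330 bp against 19411 and 17802 bp, with the same p. Within 5 kb of each other lay 26.4% of combined neighbours against 19.6% at random, a distance chosen after seeing the data (permutation p = 0.002).

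At the shorter planned distance of 2 kb the share was 1.99% against 1.38% at random (permutation p = 0.002). Once clusters less than 200 bp apart were merged, both in the list and in each random placement, the share was 1.02% against 0.727% (permutation p = 0.004), a setting chosen after seeing the data. In the list of replicate 1 alone it was 0.477% against 0.393% (permutation p = 0.46), and in that of replicate 2 alone 0.476% against 0.302% (p = 0.042). Among combined clusters above the median log2 score it was 0.474% against 0.295% (permutation p = 0.07).

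**Figure D3:**
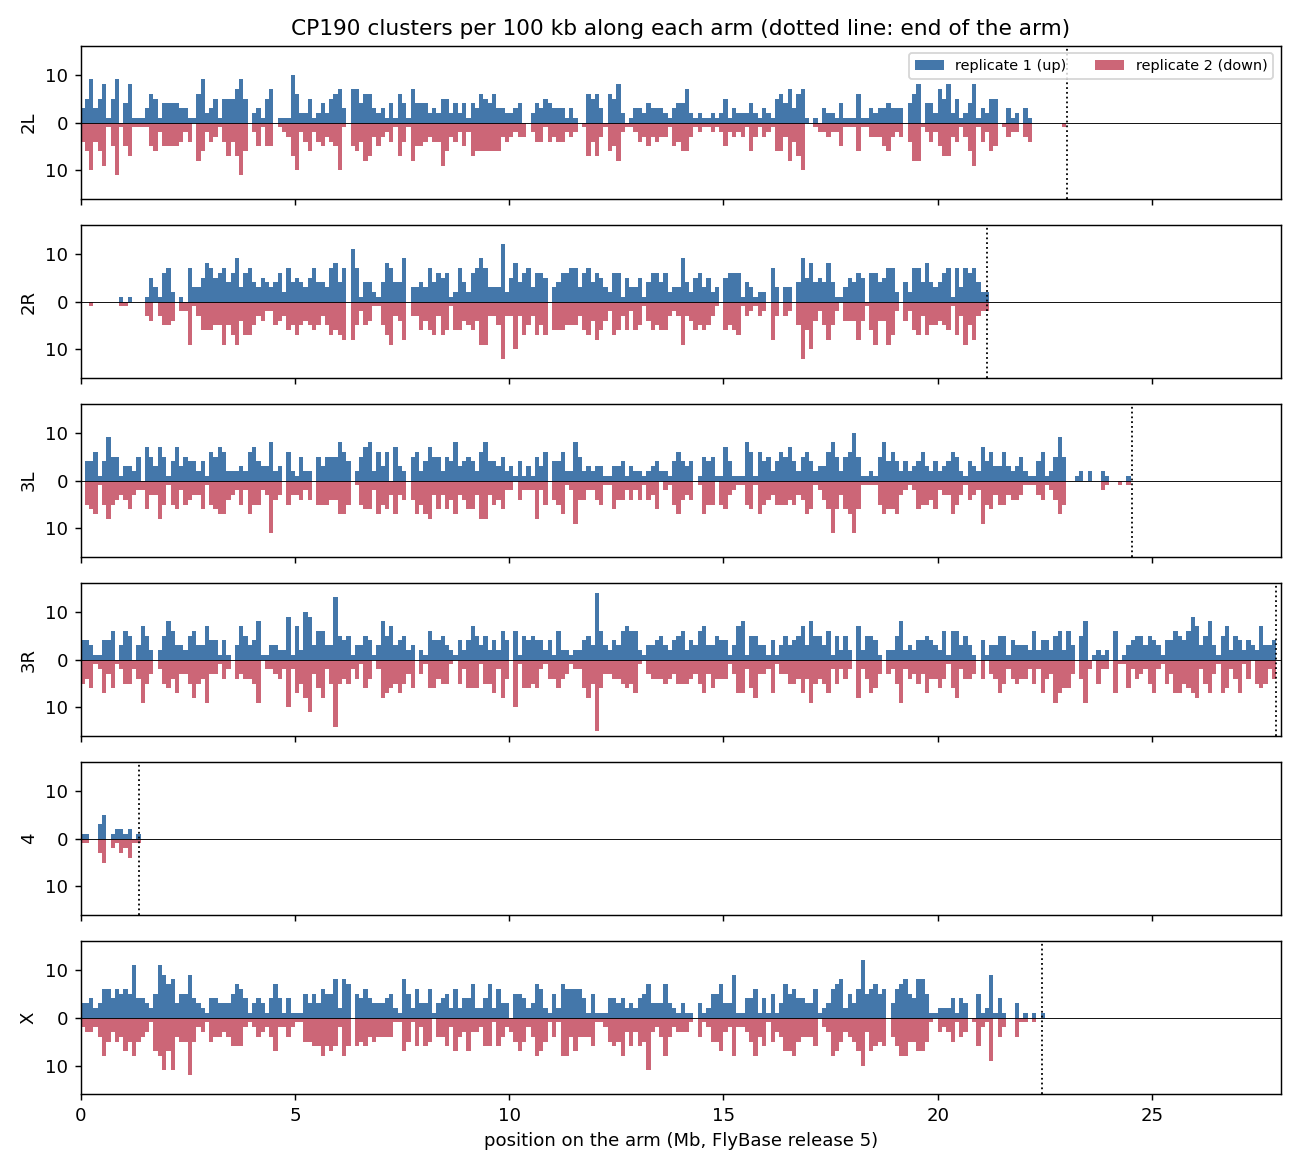
Number of clusters with a midpoint in each 100 kb window along the 6 chromosome arms, replicate 1 upward and replicate 2 downward, with a dotted line at the end of each arm. The densest window in both lists is on 3R (14 and 15 clusters), and the start of 2R and the ends of 2L, 3L and X, which face the centromere, hold few clusters.

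**Figure D4:**
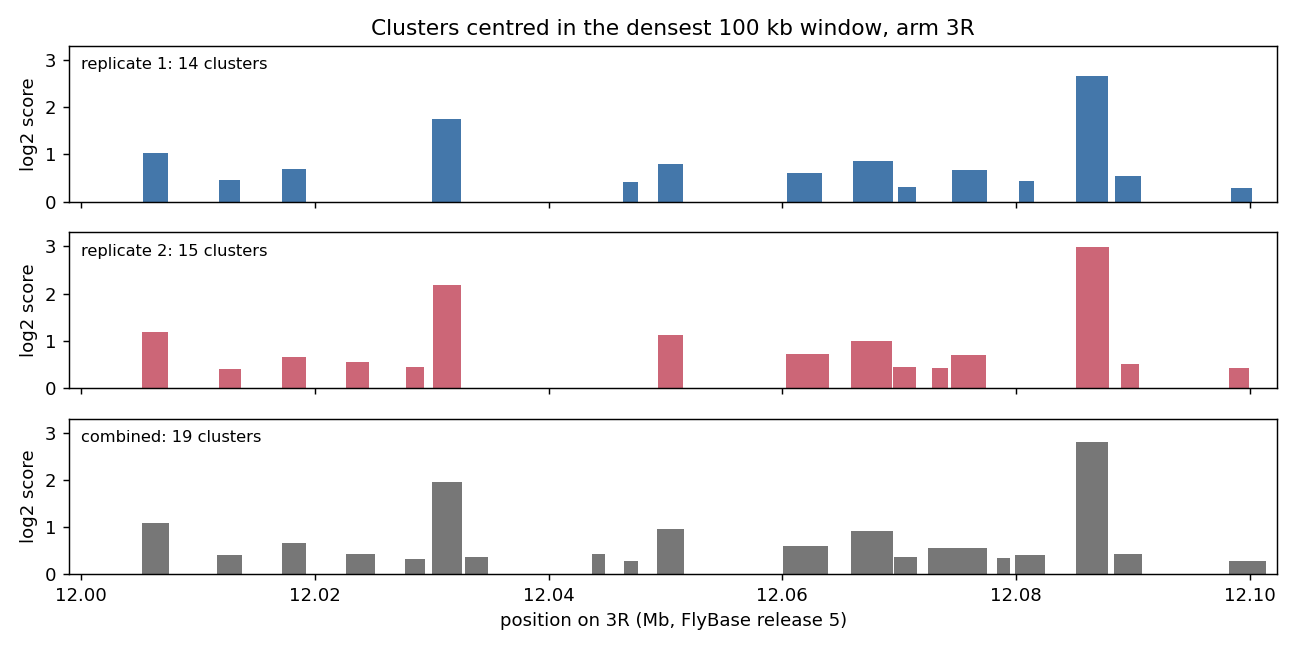
Clusters centred in the densest 100 kb window, 12000001 to 12100000 on 3R. Each bar spans a cluster from start to end (x axis, Mb) and its height is the deposited log2 score, for replicate 1 (14 clusters), replicate 2 (15) and the combined list (19). The tallest bar is the named cluster at 12085136 to 12087887.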

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

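A call was kept when direction and side of the threshold stayed the same, or when a value stayed inside the main interval. For cluster numbers and median lengths it was kept within a fixed fold margin or the SD of cluster lengths. Merging or leaving out a small part of the clusters could hardly exceed those margins. Over 21 results and 87 alternative values, 64 kept their call, 14 lost the threshold, 6 moved beyond their interval and 3 turned direction. Of these values 17 come from alternatives chosen after seeing the data, namely the 500 kb block permutation, the scaffolds alone, the 5 kb distance, the 6 arms alone, the minimum length and merging in the random placements too. Replicate overlap stayed far above the shifts in all 7 alternatives, at 69.6 to 84.8% of replicate 1 and 64.7 to 79.6% of replicate 2, while the mean of the shifts was at most 17.0 and 15.5%. The score correlation, the score difference by replicate support, cluster numbers and the density of chromosome 4 kept their calls throughout, and that of 2L lost its call only with blocks permuted in the list of replicate 2 (adjusted p = 0.087).

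The share of combined clusters found in both replicates was 45.3% when 50% of the cluster had to be covered, 77.1% above the median score and 58.3% at or above 1301 bp. The share found in neither was 16.6% above the median score, 31.5% on the 6 arms and 17.9% at or above 1301 bp. Above the median score the density ratios of 2R and 3R turned to 0.992 and 0.940, neither past the threshold, while that of X rose to 1.39. The ratios share 1 total, so the rise on X lowers those of the other arms. The order of the 4 large autosomal arms was kept, with 3L at 0.888 and 2L at 0.847. Density ratios that lost the threshold were 0.963 (3L), 1.03 (3R) and 1.05 (X) with clusters found in both replicates, and 0.938, 1.04 and 1.06 under block permutation. Leaving out either replicate list gave 0.952 to 0.965 for 3L, 1.03 to 1.05 for 3R and 1.05 to 1.05 for X. The share of neighbours within 2 kb was 1.02% after merging. It lay below random placements that were not merged (1.30%), which follows from how they were made, and above merged ones (0.727%). Above the median score it was 0.474% against 0.295% at random and lost the threshold (permutation p = 0.07), and it was 0.476 to 0.477% with either replicate left out. Leaving out a replicate here means using the other replicate's own list. Shorter lists hold fewer close neighbours by construction, and the cause of the other changes was not tested.

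No paired analysis was possible because the inputs enter only through the authors' calls and each ChIP replicate is 1 list, with labels that cross the input and ChIP numbers. Other settings fixed before the data were examined, for transcription start sites, gene lists and motifs, were not run, as no genome or annotation of release 5 was used. Read depth is unknown, so how far it limits weak clusters in each list was not measured.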

Other observations

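All tests and values in this part were chosen after the results they bear on had been seen. Counts of clusters per 100 kb window were close in the replicates (Spearman 0.865 over 1208 windows, which are not independent). The densest window of the combined list, 12000001 to 12100000 on 3R, held 19 clusters and was also the densest of both replicate lists, with 14 and 15 clusters against medians of 3 and 4. Random placement gave a mean maximum of 14.6 and reached 19 or more in few of 1000 draws (permutation p = 0.005). The next windows, 19700001 to 19800000 on 2R with 18 combined clusters and 17700001 to 17800000 on X with 16, held 8 and 7, and 8 and 5, clusters in the replicates. At the other extreme 30 windows held no combined cluster, against a mean of 2.81 at random (permutation p = 0.001, the smallest possible), and 28 of them were empty in all 3 lists.

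The ends of most large arms that face the centromere held few called CP190 clusters. The last 2 Mb before the centromere had 28.5 combined clusters per Mb on 2L, 22 on 2R, 25 on 3L and 39.5 on X, against 60.1, 74.9, 63.2 and 69.9 in the middle of the same arms. On these 4 arms it was the poorest 2 Mb window in all 3 lists. Arm 3R differed, with 64.5 per Mb near the centromere against 67.7 in its middle, and its window ranked 3 from the lowest of 13. The longest combined gap lay at 464522 to 872217 on 2R (408 kb). On X the longest gap lay at 21508276 to 21791840 (284 kb), and both replicate lists had their longest X gap there too. Chromosome 4 had median log2 scores of 0.71 and 0.83 in the replicates (19 and 24 clusters) against 0.59 and 0.62 over all arms, but 0.43 against 0.41 in the combined list (46 clusters), and these differences were not tested.

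Clusters on X had higher log2 scores than those on the 4 large autosomal arms. The median was 0.65 against 0.57 in replicate 1, a difference of 0.08 (block bootstrap 95% interval 0.06 to 0.11), and 0.69 against 0.60 in replicate 2, a difference of 0.09 (0.06 to 0.12), with a permutation p of 1e-04 in each by exchanging 500 kb blocks, the smallest possible. Clusters scoring above 1 were 1.38 times as dense on X in replicate 1 (1.11 to 1.70) and 1.33 times in replicate 2 (1.09 to 1.59). A loss of weak clusters alone would not give this if X and the autosomal arms were equally dense before the loss. That density is unknown, so a denser X that lost weak clusters is not excluded. The constant found from the autosomal arms gave whole-number ratios for 100% of the 865 and 946 X clusters of the replicates. This argues against an arbitrary separate scaling constant for X. A constant that differs by a simple ratio would give the same result and is not excluded. An even shift of the X ratios stays open too. The difference at the 90th minus that at the 10th percentile was 0.036 in replicate 1 (-0.05 to 0.12) and 0.025 in replicate 2 (-0.05 to 0.08), too wide to decide. The smallest whole-number ratios had lower median denominators on X than on these autosomal arms (143 against 196 in replicate 1, 157 against 211 in replicate 2 and 245 against 315 in the combined list), whose part in the difference was not tested, and the design names no biological contrast for X, so none was tested.

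Clusters on heterochromatic and unplaced scaffolds scored high but were found in both replicates less often than clusters on the arms, 18.3% against 47.3% in the combined list. On U 60% of clusters in replicate 1 (exact 95% interval 38.7 to 78.9%) and 53.6% in replicate 2 (33.9 to 72.5%) were shared against 93.8% and 89.4% of arm clusters matched on log2 score, while the Het scaffolds had 77.4% (58.9 to 90.4%) against 95.2% and 80% (61.4 to 92.3%) against 87.1%, the last within its interval. Length cannot be told apart as a reason, since among clusters of at least 1301 bp 51.3% of scaffold clusters (39.6 to 63.0%) and 58.4% of arm clusters were found in both, while 35.5% (24.9 to 47.3%) and 17.7% were found in neither. A candidate explanation is that many of these values are ratios of small numbers, as the smallest whole-number ratios of the 159 scaffold clusters found in neither replicate had a median numerator of 31, against 453 for the 39 found in both and 267 for 2437 arm clusters found in neither (permutation p = 1e-05 for each, the smallest possible). Those 159 were also shorter (median 1062 bp) than the 39 (2217 bp). The median numerator of the unsupported scaffold clusters of at least 1301 bp was 79 against 343.5 on the arms. As ratios are in lowest terms, a small numerator need not be a small count, and no biological explanation was tested.

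Combined clusters found in neither replicate were many. By their combined length 44.0% of the 2596 (exact 95% interval 42.0 to 45.9%) were at least as long as the shortest replicate cluster, with a median of 1587 bp. This cannot exclude length as the reason, since a replicate call of the same place can be shorter. The U cluster at 4251871 to 4254169 was 2299 bp long in the combined list, and its replicate 1 call ran from 4252760 to 4254156. Whether joint calling reached weaker places cannot be told apart from other reasons. Among clusters of at least 1301 bp those found in neither scored lower than those found in 1 replicate by a median difference of -0.014 (0.32 against 0.33, permutation p = 6e-05). Over all lengths the order was the opposite, 0.36 against 0.34. No biological explanation was tested.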
